A study of Mus musculus with 12 samples.

How the data were processed

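Messenger RNA of BV2 mouse microglial cells was measured in 12 samples, 3 each of PBS, oxy-Hb, oxy-Hb with C3a and oxy-Hb with C3aRA. Per the labels' protocols, RNA was isolated with a column kit and 1.3 ug of total RNA entered a SMARTER mRNA-seq library preparation. The tables analysed here had columns for 9 of these libraries, and the PBS samples were not analysed here. Groups and replicate numbers were taken from the labels.

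The 2 tables that the authors deposited each list 22935 Ensembl genes with raw read counts of 6 libraries, oxy-Hb beside 1 of the additions. The authors' tables also give a log2 fold change, a p-value and an adjusted p-value per gene, coordinates, and gene ontology and pathway terms. The builds GRCm38 and mm10 are named per the submitters' processing notes. The aligner, the counting tool, its strand setting and the authors' test are not given in the sources used here. The oxy-Hb counts were identical in both tables (0 differed), so the 9 libraries entered 1 fit. A spreadsheet had turned 9 gene symbols into dates, and these were restored from the identifiers. Of the identifiers, 22918 were found in a GENCODE annotation of GRCm38, and 22133 had the same start and end there. Transcript length and GC content came from that annotation and were known for 99.9% of tested genes. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and 4 tested rows share chromosome, start and counts with another row.

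Library totals ran from 12934794 to 20479002 counts. A level of 3 counts, the floor used for a count of 0, was computed per library. Replicates were compared by a chi-square of their counts per gene, which averaged 6.15 to 12.79 between replicates except for C3a replicate 2 (88.45 and 79.45), so no 2 libraries agreed within sampling noise.

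Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), leaving 14146, scaled with TMM and fitted with 1 coefficient per group. Each contrast was tested with the robust quasi-likelihood F test, and calls were made at a Benjamini-Hochberg adjusted p below 0.05 without a minimum fold. The common dispersion gave a biological coefficient of variation of 15.8%. CPM values of single genes are TMM-scaled, while CPM sums over lists and the floor come from library totals without TMM. Errors of levels are SDs over 3 libraries, and errors of log2 fold changes are SEs from the fit. On simulated counts with 200 changed genes, C3a against oxy-Hb recovered 28%, 66%, 82% and 92% of genes changed 1.5, 2, 3 and 4 fold, with 12 false calls among 13832 genes. C3aRA against oxy-Hb recovered 30%, 58%, 76% and 80%, with 5 false calls among 13821 genes, and C3a against C3aRA 20%, 66%, 58% and 86%, with 5 among 13864. All simulated libraries had the same spread per gene, with no library standing apart as C3a replicate 2 did. Recovery and false calls in the real comparisons may therefore differ.

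Gene lists fixed before the data were examined covered haem and iron, NRF2, ferroptosis, NF-kB inflammation, chemokines, interferon response, alternative activation, complement, immediate early genes, disease-associated and homeostatic microglia, antigen presentation, cholesterol synthesis and efflux, glycolysis, stress responses, heat shock, cell cycle, p53, oxidative phosphorylation, matrix, ribosomal protein, mitochondrial and histone genes, and other cells. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, again with the correlation estimated, and with fry. The red cell and astrocyte lists had too few tested genes and are given as levels.

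Genes were named by a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, or, with no calls, the 5 lowest p in each direction. It further took 20 panel genes and up to 4 genes with the lowest adjusted p from each list described. Plaur and Cfp came in as list members. Gene models without a given symbol were counted, not named, and some genes that the rule took are not reported here.

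Alternatives fixed in advance were other scalings (total count, upper quartile and the size factors of DESeq2 1.42.0), no count filter, a mean of at least 5 CPM, DESeq2's Wald test, limma-voom, fits of the 2 groups alone, the replicate number as a block, leaving out each library, stricter thresholds and protein-coding genes alone. A correction for transcript length and GC content by splines per library, library quality weights, their combinations with fits without C3a replicate 2 or of 2 groups, and pathways from the deposited terms were chosen after seeing the data.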

Results

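RNA was sequenced from BV2 cells, an immortalised mouse microglial line, after exposure to 10 µM oxyhaemoglobin (oxy-Hb), the oxygen-carrying haemoglobin that red cells release when blood enters the subarachnoid space. The series title names the C3/C3aR pathway and white matter injury after experimental subarachnoid haemorrhage. C3a, the fragment cut from complement component C3 and the ligand of the receptor C3aR, was added to oxy-Hb at 20 ug/ul according to the label, a unit that is uncertain since the dose would be very high for a peptide. C3aRA, an abbreviation that the labels do not spell out, was added at 50 µM. The 9 libraries analysed here were 3 of oxy-Hb alone, 3 of oxy-Hb with C3a and 3 of oxy-Hb with C3aRA. The 3 PBS samples of the series were not analysed here, so the response to oxy-Hb itself was not measured.

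Total counts were 15375073, 18184027 and 15889587 for oxy-Hb, 16987624, 20479002 and 17190773 for oxy-Hb with C3a, and 12934794, 16101537 and 17252848 for oxy-Hb with C3aRA. A level of 3 counts in a library equalled 0.146 to 0.232 CPM, a floor that covers counting error only. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. C3a replicate 2 stood apart. Its first principal component score was 76.3, against -23.8 to 10.8 in the other 8 libraries, and its cytosolic ribosomal protein genes summed to 54733 CPM, against 35166 to 40193 CPM. Mitochondrial transcripts took 6.06% of its counts and 5.16% to 5.93% elsewhere, and lincRNAs took 0.429% against 0.617% to 0.975%. Summed markers of other cells were low in all libraries. Astrocyte markers reached at most 0.7 CPM, red cell markers 1.9, neuronal markers 11.7, oligodendrocyte markers 37.3 and endothelial or fibroblast markers 153.3 CPM. In the 3 comparisons none of the testable lists of other cells passed, with 0 called members, and 4 oligodendrocyte, 2 neuronal and 3 endothelial or fibroblast genes tested. Adjusted over the list alone, 2 oligodendrocyte and 1 neuronal gene fell with C3a against oxy-Hb.

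**Figure D1:**
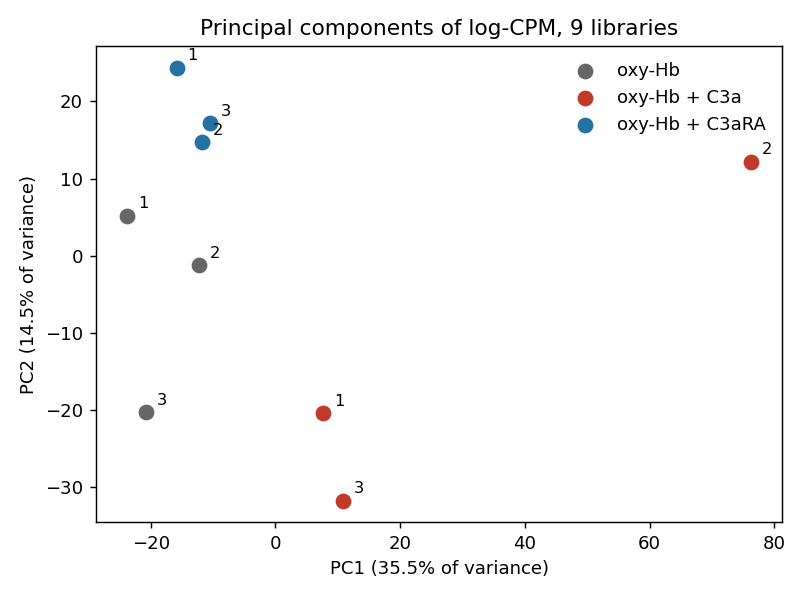
Principal component scores of the 9 libraries from log-CPM, with PC1 (35.5% of the variance) on the x axis and PC2 (14.5%) on the y axis, coloured by group and numbered by replicate. C3a replicate 2 lies at 76.3 on PC1, and the other 8 libraries lie between -23.8 and 10.8.

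The first comparison asked which transcripts changed when the C3aR ligand was added to oxy-Hb. With C3a, 558 of 14146 genes changed, 128 rising and 430 falling. Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98871204 in GRCm38), a histone methyltransferase gene, fell from 159 ± 8.20 to 57.5 ± 19.3 CPM (SD, n = 3), a log2 fold change of -1.47 ± 0.20 (SE). Its relative Kmt2a fell by 1.41 on the log2 scale. Further falls were those of Zfhx3, a homeobox transcription factor (log2 fold change -1.35), Cit, the citron kinase of cytokinesis (-1.30), Agrn, the matrix proteoglycan agrin (-1.29), and Lrp1, an endocytic receptor that also clears haem bound to haemopexin (-1.20). Dusp6, a phosphatase that limits ERK signalling, rose from 58.9 ± 3.25 to 95.4 ± 8.83 CPM (SD, n = 3), or by 0.69 ± 0.13 (SE) on the log2 scale. Mrpl18, a mitochondrial ribosome subunit (0.74), Ranbp1, a regulator of nuclear transport (0.72), Tuba1b, an alpha-tubulin (0.70), Plaur, the urokinase receptor (0.65), and Itgam, the integrin chain CD11b (0.69), also rose. Plaur stood at 0.375 and Itgam at 0.383 without C3a replicate 2, and both calls were lost without any 1 of the oxy-Hb or C3aRA libraries, that of Itgam also after the length and GC correction.

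Among gene lists fixed before the data were examined, the NRF2 oxidative stress list stood higher with C3a (median log2 fold change 0.30, camera adjusted p = 3.56e-06; adjusted p = 0.657 with an estimated correlation). Of its 31 genes 3 rose, namely Pgd, a pentose phosphate enzyme (0.44), Cat, the catalase gene (0.44), and Srxn1, which repairs peroxiredoxins (0.57). Adjusted over the list alone, 12 rose and 1 fell. Over the 9 fits that left out 1 library, the Pgd call held in 3 and those of Cat and Srxn1 in 2 each. Without C3a replicate 2, whose NRF2 genes summed to 10581 CPM against 7207 to 8218 CPM in the other 8 libraries, the median was 0.15. The list of disease-associated microglia and phagocytosis was also higher (median 0.28, adjusted p = 1.42e-05; adjusted p = 0.657 with an estimated correlation), with 2 of 37 genes rising, over all genes and adjusted over the list alone. Without C3a replicate 2, whose members summed to 35830 CPM against 25782 to 28694 CPM with oxy-Hb (not TMM-scaled), this median was 0.10. The genes were Lpl, lipoprotein lipase (0.42), and Fcgr1, an IgG receptor (0.56), while Trem2 (0.39, adjusted p = 0.0818) and Apoe (0.36, adjusted p = 0.0886) did not pass in the edgeR test. Heat shock genes had a median of 0.29 (adjusted p = 3.66e-05; adjusted p = 0.657 with an estimated correlation). None of the 19 passed over all genes in the fit of 9 libraries, 10 rose with C3a replicate 2 left out and 3 after the length and GC correction, and 13 rose adjusted over the list alone.

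Lists of energy metabolism and translation moved together with C3a replicate 2. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of 0.30 (camera adjusted p = 1.23e-09; adjusted p = 0.657 with an estimated correlation), and 2 of 61 rose, among them Atp5b (0.37); adjusted over the list alone, 13 rose. Without C3a replicate 2 their median was 0.10. Cytosolic ribosomal protein genes had a median of 0.27 (adjusted p = 9.74e-07; adjusted p = 0.671 with an estimated correlation), -0.01 without that library, which ended the call, and 0.44 without C3a replicate 1. Of these 75 genes Rpl30 alone rose (0.58), and 0 passed adjusted over the list alone. Rpl30 stood at 0.325 without C3a replicate 2, and its call was lost without any 1 of the oxy-Hb or C3aRA libraries and after the length and GC correction. Mitochondrially encoded mRNAs had a median of 0.37 (adjusted p = 0.0168; adjusted p = 0.671 with an estimated correlation), and 0.14 without that library, again with the call lost, as it also was without oxy-Hb replicate 1 and after the length and GC correction. mt-Nd1 was the 1 of 12 that rose, also adjusted over the list alone. Its call held in 1 of the 9 fits that left out 1 library, with log2 fold changes from 0.489 to 0.878. Ribosomal protein genes and mt-Nd1 share reads with pseudogene copies, so their counts are uncertain.

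The remaining lists did not pass with C3a against oxy-Hb (camera adjusted p from 0.0521 for interferon-stimulated genes to 0.865 for alternative activation and repair). Immediate early genes and MAPK feedback genes went both ways, with Dusp6 and Rgs2 (0.59), a regulator of G protein signalling, rising, and Junb, an AP-1 subunit (-0.76), and Dusp4 (-0.51) falling. Without C3a replicate 2, 2 rose and 11 fell of these 37. Itgam, with the dependence given above, was the 1 of 20 complement genes that rose, while C3ar1 (0.32, adjusted p = 0.117), C5ar1 (0.51, adjusted p = 0.116) and C3 (0.14, adjusted p = 0.707) did not pass in edgeR. Of 38 inflammatory and NF-kB genes, Ikbke fell (-0.56). Stat2 (-0.69) fell among 39 interferon-stimulated genes, Nlrc5 (-0.58), an activator of MHC class I genes, among 19 antigen presentation genes, and Bcl2l11 (-0.63), a pro-apoptotic BH3-only gene, among 28 p53 and apoptosis genes. Among 44 stress response genes Pdia3 (0.46) rose and Syvn1 (-0.87) fell, and among 24 matrix genes Plaur rose and Adam8 (-0.56) fell. Lrp1 fell among 25 haem and iron genes, and Lpl rose among 23 lipid efflux or storage genes. Of 23 homeostatic microglia genes Itgam rose, with a list median of 0.09 and a mean of -0.05, and the endothelial or fibroblast list had a median of -0.03 and a mean of 0.41. No member was called among ferroptosis, chemokine, alternative activation, cholesterol synthesis, glycolysis and hypoxia, cell cycle or histone genes in the fit of 9 libraries. With C3a replicate 2 left out, 11 cell cycle genes rose and 3 fell, 4 cholesterol synthesis genes rose and 1 fell, and 3 glycolysis and hypoxia genes rose. In that fit 3 stress response genes rose and 5 fell, and 5 p53 genes fell. After the length and GC correction 5 glycolysis and hypoxia genes rose. The 20 panel genes fixed in advance, Hmox1, Tnf, Il6 and Nos2 among them, did not pass, with adjusted p from 0.0715 for Actb to 0.758 for Fth1. Il1b, at 0.610 ± 0.241 CPM (SD, n = 3) with C3a, lay close to the floor.

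Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Groups did not overlap for 27.8% of genes, against 10% expected for a single gene by chance. The share of falls, 77.1%, was 95.1% with total count scaling and 49.3% after a correction for transcript length and GC content, which left Kmt2d at -0.84. The count was 99 in a fit of the 2 groups alone, 1243 with DESeq2, 54, 107 and 307 without oxy-Hb replicates 1, 2 and 3, 1638, 1395 and 444 without C3a replicates 1, 2 and 3, and 322, 321 and 296 without C3aRA replicates 1, 2 and 3. Of 40 named calls, 5 held whichever of the 9 libraries was left out, among them those of Agrn, Cit, Kmt2d and Zfhx3. The authors' deposited table held 508 calls, 87 higher and 421 lower, of which 456 were shared with the same sign.

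The next comparison asked which transcripts changed when C3aRA was added to oxy-Hb. In the fit of all 9 libraries no gene passed the edgeR test (0 calls, lowest adjusted p = 0.467). An unadjusted p below 0.05 was reached by 1153 genes where chance gives 707, DESeq2 called 1 gene, and limma-voom called 0. Groups did not overlap for 22.9% of genes, against 10% expected for a single gene by chance. Genes are not independent and the share was not computed for other splits, so it does not show an effect of C3aRA. Nor do 0 calls in this fit show that the groups were alike. Gene lists moved, and the lowest p was that of the integrated stress and unfolded protein responses (median log2 fold change 0.19, camera adjusted p = 2.24e-10; adjusted p = 0.59 with an estimated correlation). Hspa5, the chaperone BiP of the endoplasmic reticulum, stood at 1477 ± 267 CPM with C3aRA and 969 ± 57.9 CPM without it (SD, n = 3), a log2 fold change of 0.61 ± 0.13 (SE). In the same list Sars, a seryl-tRNA synthetase (0.37), and Sel1l, of the degradation pathway for misfolded proteins (0.34), were on the higher side and Ddit4 (-0.62) on the lower side. In a fit of these 2 groups alone 603 genes passed, 338 higher and 265 lower, and 12 of the 44 stress response genes were higher and 1 lower. In the fit of 9 libraries 1 of the 44 rose adjusted over the list alone.

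Cholesterol synthesis and SREBP target genes had a median of -0.11 with C3aRA (adjusted p = 0.000334; adjusted p = 0.59 with an estimated correlation), led by Fasn, fatty acid synthase (-0.67), Hsd17b7 (-0.57) and Scd2 (-0.38). None passed over all genes, 5 fell adjusted over the list alone, and 6 of 31 were lower in the 2-group fit. Inflammatory and NF-kB genes had a median of 0.17 (adjusted p = 0.000334; adjusted p = 0.59 with an estimated correlation). Tnf stood at 224 ± 20.1 against 166 ± 20.6 CPM (SD, n = 3), and Lcn2 (0.69), Il1rn (0.36) and Csf1 (-0.46) were the other members with the lowest p. Adjusted over the list alone, 3 rose and 1 fell. Antigen presentation genes had a median of 0.28 (adjusted p = 0.000334; adjusted p = 0.59 with an estimated correlation), with H2-K1 at 0.31 and H2-D1 at 0.28, 2 class I genes that share reads with paralogs, and Cd40 at 0.32. Adjusted over the list alone, 0 antigen presentation, ribosomal protein, disease-associated or ferroptosis genes passed, and 1 p53 gene rose. Smaller shifts that passed were those of ribosomal protein genes (median 0.11, adjusted p = 0.00111; adjusted p = 0.991 with an estimated correlation) and of disease-associated genes (median 0.10, adjusted p = 0.0108; adjusted p = 0.905 with an estimated correlation), in which Spp1, osteopontin (0.37), was higher and Ccl6 (-0.66) lower. The p53 and apoptosis list (median 0.13, adjusted p = 0.0304; adjusted p = 0.59 with an estimated correlation) and the ferroptosis list (median 0.15, adjusted p = 0.0476; adjusted p = 0.59 with an estimated correlation) also passed. In the former Plk2 (0.58) and Gdf15 (0.50) were on the higher side and Aen (-0.46) on the lower, and in the latter Sat1 (0.41) and Chac1 (0.61) on the higher side and Tfrc (-0.38) on the lower.

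The other lists did not pass with C3aRA against oxy-Hb (camera adjusted p from 0.0543 for immediate early genes to 0.988 for histones). Chemokine genes had a median of 0.21 (adjusted p = 0.0564), with Ccl3 at 0.44 and Ccl7 at 0.45. For haem and iron, NRF2, interferon-stimulated, complement, homeostatic, glycolysis, cell cycle, mitochondrially encoded, histone and endothelial or fibroblast genes the median, the mean and the test differed in sign or were 0. The genes with the lowest p, none of them passing in the fit of 9 libraries, were Hspa5, Pde6c, Sp140 (0.60), Serpina3g and Pdcd4 (0.52) on the higher side, and Gpr132 (-0.70), Tifab (-1.02), Trim39 (-0.60), Ina (-1.02) and Capn15 (-0.88) on the lower side. In the authors' deposited table, whose test is not given, the adjusted p was 2.63e-06 for Gpr132 and 0.00677 for Hspa5. Trim39, Sp140, Pdcd4, Ina, Capn15 and Tifab lay between these values there, and Pde6c and Serpina3g did not pass. Pde6c had no count in the 3 oxy-Hb libraries and 0.799 ± 0.288 CPM with C3aRA (SD, n = 3), and Serpina3g had 0.0386 ± 0.0338 and 0.685 ± 0.104 CPM, both close to the floor. C3ar1 (-0.14, adjusted p = 0.801) and the other 19 panel genes did not pass in edgeR, with adjusted p from 0.479 for Tnf to 0.998 for Nos2 and Mrc1.

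The outcome of this comparison depended on the libraries in the fit: without C3a replicate 2, which belongs to neither group, 475 genes passed. The authors' deposited table held 715 calls, 473 higher and 242 lower. The ferroptosis call was lost without oxy-Hb replicate 2 or any 1 of the 3 C3aRA libraries, the p53 call without oxy-Hb replicate 2 or C3aRA replicate 1, and the disease-associated call without oxy-Hb replicate 3. The p53 median was 0.07 without oxy-Hb replicate 2, the disease-associated median 0.05 without oxy-Hb replicate 3, and the ribosomal median 0.17 without oxy-Hb replicate 2.

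The last comparison tested the difference between both additions directly. It gave 876 genes, 406 higher and 470 lower with C3a than with C3aRA. Among called immediate early genes, Junb stood at 43.7 ± 7.19 against 91.7 ± 7.46 CPM (SD, n = 3), a log2 fold change of -1.07 ± 0.15 (SE) with C3a. Zfp36, which destabilises cytokine mRNAs, differed by -1.0 and Dusp4 by -0.80, while Rgs2 was higher by 0.82. Il6 stood at 2.73 ± 0.0766 against 6.54 ± 0.204 CPM and Tnf at 144 ± 8.12 against 224 ± 20.1 CPM (SD, n = 3), log2 fold changes of -1.26 ± 0.24 and -0.63 ± 0.11 (SE). Mt1, a metallothionein gene, was higher with C3a by 1.27 ± 0.18 (SE), and Ccl6, a chemokine (1.08), Trem1, a myeloid activating receptor (1.06), Tnfsf13b, the cytokine BAFF (1.06), and Mmp12, macrophage elastase (0.97), were higher too. C3ar1 (ENSMUSG00000040552, chromosome 6, 122847138 to 122856161), the C3a receptor gene, was higher with C3a at 84.8 ± 9.05 against 61.6 ± 0.976 CPM (SD, n = 3; log2 fold change 0.46, edgeR adjusted p = 0.0355).

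**Figure D2:**
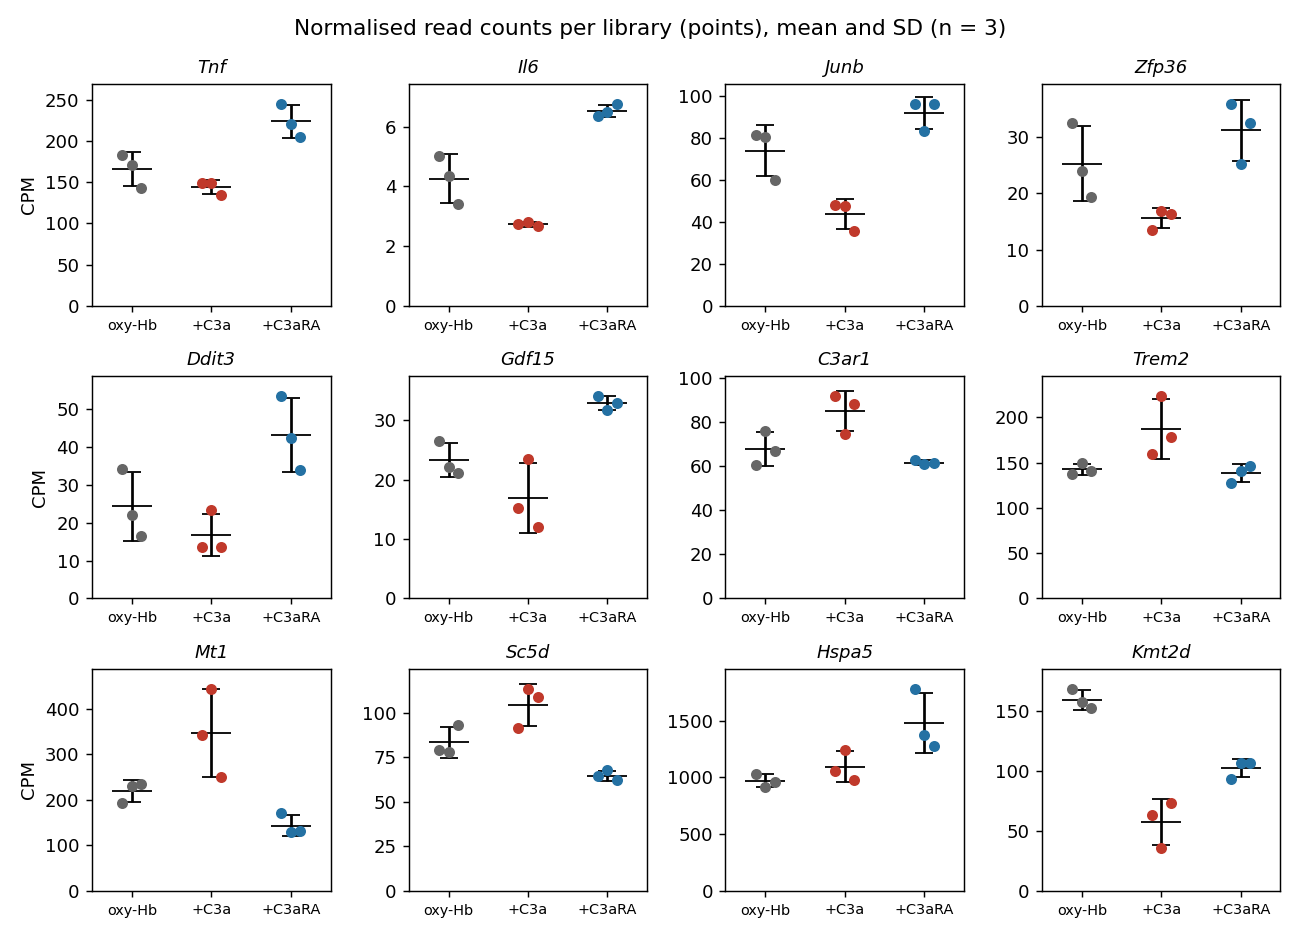
Normalised read counts in CPM (y axis, from 0) of 12 genes in each library of the 3 groups, with points for libraries and bars for the mean and SD (n = 3). Tnf, Il6, Junb, Zfp36, Ddit3 and Gdf15 were lower with C3a than with C3aRA, and C3ar1, Trem2, Mt1 and Sc5d were higher. Hspa5 with C3aRA (1477 CPM) stood above oxy-Hb (969 CPM) without passing in the fit of 9 libraries, and Kmt2d fell with C3a from 159 to 57.5 CPM.

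Inflammatory and NF-kB genes as a list were lower with C3a than with C3aRA (median log2 fold change -0.22, camera adjusted p = 0.00313; adjusted p = 0.693 with an estimated correlation). Of 38, 5 were lower, Il6, Tnf, Ptgs2 (-0.87), Relb (-0.77) and Nfkbiz (-0.75), and 1 was higher; adjusted over the list alone, 8 were lower and 1 higher. The list median was -0.12 without C3a replicate 2. None of the 5 stayed called without C3aRA replicate 1, 1 did without C3aRA replicate 3, and 3 did without C3a replicate 3 or C3aRA replicate 2. All 5 did without C3a replicate 1, and 4 without C3a replicate 2. Over these fits the medians of the 5 ran from -0.93 to -0.70. Immediate early and MAPK feedback genes were lower (median -0.25, adjusted p = 0.00156; adjusted p = 0.703 with an estimated correlation), 2 of 37 being higher and 4 lower, or 2 and 9 adjusted over the list alone, and 2 and 14 with C3a replicate 2 left out. The stress response list was lower (median -0.12, adjusted p = 0.0119; adjusted p = 0.703 with an estimated correlation), with 7 of 44 lower and 1 higher, or 9 and 1 adjusted over the list alone. Ddit3, the transcription factor CHOP (-1.36), Ppp1r15a, the GADD34 phosphatase subunit (-0.85), Nupr1 (-0.59) and Herpud1 (-0.53) were among the lower ones, and without C3a replicate 2 the 7 became 17. The p53 and apoptosis list was lower (median -0.07, adjusted p = 0.0173; adjusted p = 0.693 with an estimated correlation), 6 of 28 being lower, or 7 adjusted over the list alone, with Bbc3 (-1.06), which encodes PUMA, Gdf15 (-0.96), Plk2 (-0.67) and Bcl2l11 (-0.60) as examples. Without C3a replicate 3 the immediate early, stress response and p53 calls were lost, and the stress response call also without C3a replicate 1. The immediate early median was -0.15 without C3a replicate 3, and the stress response median -0.03, -0.25 and -0.01 without C3a replicates 1, 2 and 3. The p53 median was -0.18, -0.18 and -0.04 without C3a replicates 1, 2 and 3, and -0.04 and -0.17 without C3aRA replicates 1 and 3.

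Cholesterol synthesis genes were higher with C3a than with C3aRA (median 0.20, camera adjusted p = 0.000187; adjusted p = 0.537 with an estimated correlation). Of 31, 7 were higher and 0 lower, or 9 and 1 adjusted over the list alone, and 12 and 1 with C3a replicate 2 left out. They included Sc5d (0.69), Acat2 (0.70), Hsd17b7 (0.81) and Hmgcs1 (0.54), which act in sterol synthesis. NRF2 genes were higher (median 0.27, adjusted p = 2.85e-05; adjusted p = 0.693 with an estimated correlation), with 5 of 31, or 8 adjusted over the list alone, among them Mt1, Pgd (0.55), Srxn1 (0.66) and G6pdx (0.49). Their median was 0.13 without C3a replicate 2. Heat shock genes were higher (median 0.24, adjusted p = 0.000493; adjusted p = 0.682 with an estimated correlation), with Dnaja1 (0.62) and Dnajb1 (0.67) called of 19, or 8 higher and 1 lower adjusted over the list alone. The disease-associated list had a median of 0.17 (adjusted p = 0.0177; adjusted p = 0.725 with an estimated correlation) with Ccl6, Fcgr1 (0.67) and Trem2 (0.44, edgeR adjusted p = 0.0495) higher of 37, or 5 adjusted over the list alone. Without C3a replicate 3 this median was 0.29, and without C3a replicate 2 it was -0.01 and the call was lost, as it also was after the length and GC correction. Interferon-stimulated genes had a median of 0.21 (adjusted p = 0.0472; adjusted p = 0.703 with an estimated correlation), with Irgm1 (0.55) and Cmpk2 (1.12) higher and Tap1 (-0.68) lower of 39, or 4 and 2 adjusted over the list alone. That call was lost without C3a replicates 1 or 3 or C3aRA replicates 1 or 2, and after the length and GC correction.

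Oxidative phosphorylation genes (median 0.27, adjusted p = 1.69e-07; adjusted p = 0.703 with an estimated correlation), ribosomal protein genes (0.17, adjusted p = 0.0119; adjusted p = 0.725 with an estimated correlation) and mitochondrially encoded mRNAs (0.43, adjusted p = 0.0119; adjusted p = 0.703 with an estimated correlation) were higher with C3a. Without C3a replicate 2, in which the ribosomal and mitochondrial shares were highest, these medians were 0.06, -0.12 and 0.10. The calls of oxidative phosphorylation and mitochondrial genes were lost there, and the ribosomal list passed there as lower with C3a (adjusted p = 4.09e-05, from 1.12e-06 to 0.725 over its settings). The ribosomal and mitochondrial calls were also lost without C3aRA replicate 3, where the mitochondrial median was 0.29, and after the length and GC correction. The ribosomal median was 0.32 and 0.30 without C3a replicates 1 and 3. Over all genes 4 of 61, 0 of 75 and 2 of 12 members were higher, and 6, 0 and 4 adjusted over the list alone, with Atp5k (0.94) and mt-Cytb (0.70) as examples. The remaining lists did not pass (adjusted p from 0.0677 for antigen presentation to 0.975 for ferroptosis). Their called members included H2-Q4 (-1.07), which shares reads with paralogs, the properdin gene Cfp (0.68), Plaur (0.79, and 0.511 without C3a replicate 2), the growth factor Igf1 (0.42), Slc16a3 (0.58), Ccne1 (0.54) and Ccne2 (0.85) of the cell cycle, Lpcat3 (0.51) and Hist1h4i (0.78). In the matrix, glycolysis and hypoxia, cell cycle and ferroptosis lists Adam8, Pfkfb3, Cenpa and Ptgs2 were called lower. No haem and iron or homeostatic gene was called in the fit of 9 libraries, and 3 and 2 were higher and 4 and 0 lower with C3a replicate 2 left out. Cell cycle calls went from 4 higher and 2 lower to 16 and 3 in that fit. The median and the test had opposite signs for ferroptosis, and the median (-0.11) and mean (0.06) for alternative activation. Of 20 panel genes, Actb (0.68), a common reference gene, passed besides C3ar1, Tnf, Il6 and Trem2, and the other 15 had adjusted p from 0.08 for C5ar1 to 0.962 for Mmp9.

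**Figure D3:**
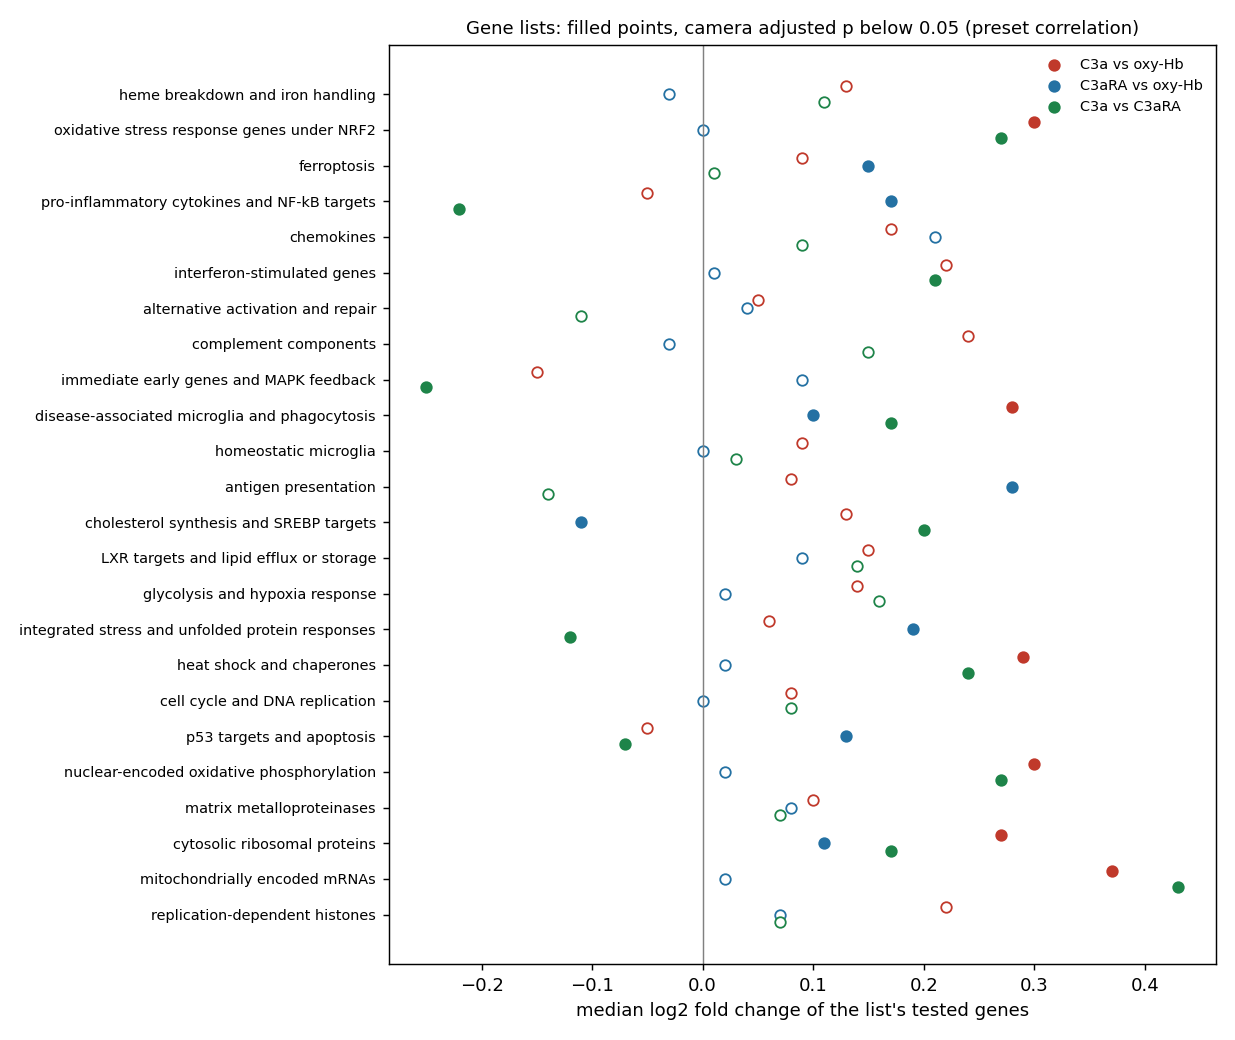
Median log2 fold change of the tested genes of 24 lists (x axis) in the 3 comparisons, coloured by comparison, with filled points where camera's adjusted p with a preset correlation was below 0.05. The stress response list stood at 0.19 for C3aRA against oxy-Hb and at -0.12 for C3a against C3aRA, and no list passed with an estimated correlation.

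The calls came from edgeR's quasi-likelihood test in the fit of 9 libraries. Groups did not overlap for 28.8% of genes, against 10% expected for a single gene by chance. The count of calls was 118 in a fit of the 2 groups alone and 1446 with DESeq2. It was 560, 390 and 575 without oxy-Hb replicates 1, 2 and 3, 1670, 1827 and 420 without C3a replicates 1, 2 and 3, and 53, 175 and 149 without C3aRA replicates 1, 2 and 3. The share of lower genes was 53.7%, and 38.8% after the length and GC correction. Of 70 named calls, 12 held whichever of the 9 libraries was left out, Junb, Dusp4, Rgs2, Mt1, Trem1, Tnfsf13b, Gtpbp2, Fzd5, Cry2, Sh2d6, Dnah6 and Agrn. The C3ar1 call was lost without either oxy-Hb replicate 2 or 3, C3a replicate 1 or 3, or any C3aRA library, and so was that of Trem2 without any oxy-Hb or C3aRA library or C3a replicate 3. Trem2 stood at 0.283 without C3a replicate 2, and the Plaur call was lost without any 1 of the C3aRA libraries.

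**Figure D4:**
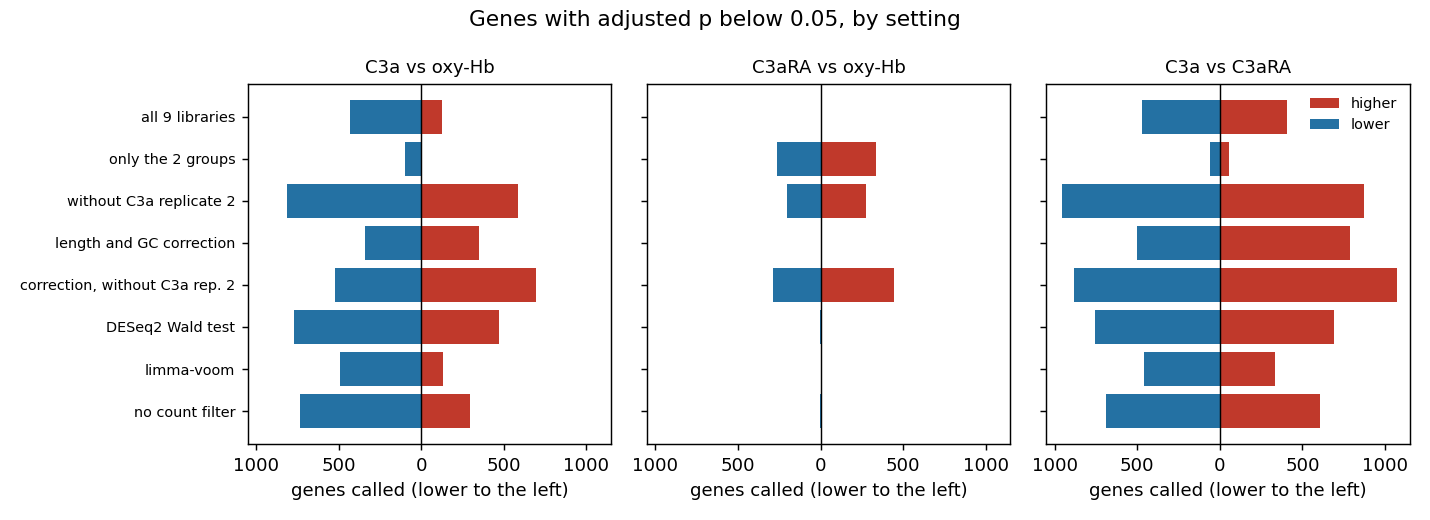
Genes with an adjusted p below 0.05 (x axis, higher to the right and lower to the left of 0) under 8 settings in the 3 comparisons. C3aRA against oxy-Hb gave 0 calls in the fit of 9 libraries, 603 in the fit of its 2 groups alone and 475 without C3a replicate 2.

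Whether C3a and C3aRA moved genes in opposite directions from oxy-Hb was asked across genes. The log2 fold changes of both additions had a Pearson r of 0.383 and a Spearman rho of 0.321 over 14146 genes, and 60.9% had the same sign. Genes are not independent replicates, and both comparisons share the oxy-Hb libraries. In 100 simulated sets without changes, all libraries, oxy-Hb included, were drawn around the oxy-Hb mean with the same spread per gene in every group. There r was 0.496 with an SD of 0.011, rho 0.457 and the same-sign share 66.6%. The covariance was 0.063, against 0.0463 in the simulation, a difference of 0.0168. For 10109 genes at a mean of 5 CPM or more, r was 0.297 against 0.499, and the covariances were 0.02 and 0.0164, a difference of 0.00359. The 3 oxy-Hb libraries could not be split into 2 groups of 2, so part of the difference may come from the shared controls. Through C3a replicate 2 the C3a group was also more uneven than the equal spread of the simulation. The observed r lay below the simulated value and the observed covariance above it, so these values do not decide whether the additions acted in opposite directions.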

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

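The length and GC correction, the quality weights and their combinations were chosen only after results were seen; the other settings were fixed before. C3a against oxy-Hb gave 558 genes, and 1033 without a filter, 1243 with DESeq2, 99 in the 2-group fit, 1636 with quality weights, 1220 with the correction without C3a replicate 2, 33 in the corrected 2-group fit, 101 at an adjusted p below 0.01 and 121 at 2-fold or more. C3aRA against oxy-Hb gave 0, and 8, 1, 603, 442, 732 and 993 under the first 6 of these settings in turn. C3a against C3aRA gave 876, and 1446 with DESeq2, 118 in the 2-group fit, 1995 with quality weights, 1951 with the correction without C3a replicate 2, 88 and 108 at the stricter thresholds. Leaving out 1 library gave 54 to 1638, 0 to 475 and 53 to 1827 genes. The stricter thresholds lower counts by construction, and for the rest the cause was not tested. The settings do show that the 0 of C3aRA against oxy-Hb depended on C3a replicate 2, a library in neither group. That library enters this test through the spread shared by all groups. The 0 became 475 without it, 442 with quality weights, where its weight was the lowest (0.14), and 603 without the C3a group. It stayed 0 whichever other library was left out. At these depths the self-test, whose simulated libraries had an equal spread and no uneven library, recovered 20% to 30% of 1.5-fold changes.

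Gene lists called numbered 6, 8 and 12 (C3a and C3aRA against oxy-Hb, C3a against C3aRA). With an estimated correlation 0, 0 and 0 were called, with fry 1, 0 and 2, with the correction without C3a replicate 2 the first became 10, and leaving out 1 library gave 6 to 13, 6 to 10 and 9 to 12. The correlation of fold changes, 0.383, was 0.297 at 5 CPM or more, 0.522 among called genes and 0.435 to 0.487 without 1 oxy-Hb library. Sets simulated without changes gave 0.503 for the called genes (SD 0.046, their selection not simulated) and 0.595 to 0.599 without 1 oxy-Hb library.

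Whether replicate numbers pair the samples stays open: 9 same-number pairs correlated at -0.04 to 0.17, 2 of them over 0.1, and 5 correlated best with their own number. Pairs of oxy-Hb and C3a, at 0.03, 0.17 and 0.11, each exceeded the other numbers (at most -0.01, -0.11 and 0.08). Pairs with C3aRA went both ways. With the replicate number as a block the counts were 835, 0 and 1210, and with the correction as well 1077, 24 and 1645.

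Over 228 results of named genes, 5435 values under other settings held 1 reversal, Fth1 in C3a against oxy-Hb at -0.27 (adjusted p = 0.0148, 0.0148 to 0.984 over its settings) with the correction without C3a replicate 2, for which the cause was not tested; 37 further sign changes were uncalled under both settings. Alternatives for tables without counts and those of oxy-Hb against PBS were not run.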

Other observations

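Tests of the splits of samples and of depth were fixed beforehand, and the pathway tests and the other tests below were chosen only after the results were seen.

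RNA processing genes stood higher with C3a than with C3aRA. Among 299 pathways named in the deposited tables, 34 passed camera in this comparison, led by the Spliceosome pathway (adjusted p = 3.13e-08; adjusted p = 0.703 with an estimated correlation). Of its 124 genes 22 were higher and 1 lower, with a median log2 fold change of 0.23, and the adjusted p was 1.1e-08 with the length and GC correction and without C3a replicate 2. RNA transport had 12 of 146 genes higher and 1 lower (adjusted p = 0.00947; adjusted p = 0.703 with an estimated correlation), Pyrimidine metabolism 7 of 83 higher and 0 lower (adjusted p = 0.00258; adjusted p = 0.703 with an estimated correlation), and Steroid biosynthesis 4 of 13 higher and 0 lower (adjusted p = 0.00982; adjusted p = 0.703 with an estimated correlation). The Proteasome pathway, with 3 of 43 higher (adjusted p = 1.36e-05; adjusted p = 0.703 with an estimated correlation), had an adjusted p of 0.163 with the correction and without C3a replicate 2.

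With C3a against oxy-Hb 65 pathways passed, among them Spliceosome (5 of 124 genes rose and 2 fell, adjusted p = 1.81e-06; adjusted p = 0.44 with an estimated correlation), Biosynthesis of amino acids (2 of 57 rose, adjusted p = 1.72e-05; adjusted p = 0.385 with an estimated correlation) and Phagosome (6 of 107 rose, adjusted p = 0.000349; adjusted p = 0.533 with an estimated correlation). With C3aRA against oxy-Hb 17 passed, with 0 called genes, among them Aminoacyl-tRNA biosynthesis (median 0.10, adjusted p = 0.00475; adjusted p = 0.771 with an estimated correlation) and Lysosome (median 0.09, adjusted p = 0.00504; adjusted p = 0.852 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, was uneven within the C3a group, at 114.5 CPM in replicate 1 and 11.9 and 12 CPM in the other 2.

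C3a replicate 2 deviated from its group by 1.49 times the largest deviation among the other 8 libraries, and its deviations correlated with transcript length across genes (rho = -0.66). The other C3a libraries were measured from means that hold this library, and against libraries outside its group the ratio was 2.12. After the length and GC correction both ratios were still 1.38 and 1.89, so these trends do not account for all of the deviation. With libraries thinned to the smallest total they were 1.48 and 2.09, which argues against depth. Of 5 marker lists of other brain or blood cells 0 were highest in this library, which argues against such cells. RNA integrity and a response of that culture to C3a stay open and were not tested, since the labels give neither.

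More genes fell than rose with C3a against oxy-Hb, 77.1% of calls. Among protein-coding genes, the 388 called falls had a median transcript length of 5329 nt and 55.2% GC, and the 115 called rises 2458 nt and 48.3%. All tested protein-coding genes had 3371 nt and 49.6%. After the length and GC correction 350 genes rose and 341 fell (49.3% falls), and 274 of the 430 falls stayed called, their median log2 fold change going from -0.78 to -0.54, so such a trend may account for part of their size. Without C3a replicate 2, 584 rose and 811 fell (58.1%), with 426 of the 430 falls still called, so the share shrank through added rises. In the fit of the 2 groups alone falls were 97% of 99 calls, and 90.9% of 33 with the correction, so length and GC stay open as the cause of the excess, as does a real fall of long transcripts with C3a. Less intron-derived RNA also stays open: 573 sense-intronic and unclassified (TEC) models had a median of -0.41 after the correction and without replicate 2, but falls were 43% of calls there, so that fit holds no excess to explain.

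The 5 NF-kB list genes called lower with C3a than with C3aRA, Il6, Tnf, Ptgs2, Relb and Nfkbiz, had a median log2 fold change of -0.77. After the length and GC correction the median of the whole list kept 89.9% of its size, going from -0.22 to -0.20, which argues against that trend as the cause. Dependence on a single library stays open: the median of the whole list kept 54.1% of its size without C3a replicate 2, and called genes among the 5 numbered 5, 4 and 3 without C3a replicates 1, 2 and 3 and 0, 3 and 1 without C3aRA replicates 1, 2 and 3. Against oxy-Hb the list median was -0.05 with C3a (camera adjusted p = 0.497, 17 genes higher and 21 lower) and 0.17 with C3aRA. The whole list thus shifted little with C3a, and these values do not show that both additions acted oppositely on it. The labels also do not say what C3aRA acts on. Oxy-Hb lay between both groups for Il6 and Tnf. Both were among genes called for the difference between the additions, which favours such a middle place. Neither gene differed from oxy-Hb with a call in the fit of 9 libraries, although Tnf with C3aRA passed in the fit of 2 groups and without C3a replicate 2.

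Other splits of the 6 libraries of each comparison were refitted. The real split of C3a and oxy-Hb was the 1 of 10 with as many as 558 calls, and the highest other split gave 0. For C3a and C3aRA the real split was the 1 of 10 with as many as 876, and the highest other gave 0. For C3aRA and oxy-Hb all 10 of 10 gave at least the real 0, the highest other giving 1, and in the fit of these 2 groups alone the real split was the 1 of 10 with as many as 603, the highest other giving 1. With 10 splits the share is never under 0.1, too few for a share under 0.05.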
